A study of Mus musculus with 12 samples.

How the data were processed

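Expression was measured in 12 single mouse morulae, 1 per array, on single-colour Agilent arrays labelled with Cy3. Per the labels, RNA was extracted with TRIzol and amplified in a pair of rounds to aminoallyl RNA. The groups were male IVF (2), female IVF (2), siCont clones (4) and siXist clones (4), taken from the labels, which also give the sex of each embryo. Per the file headers, the scanner files hold intensity from Agilent Feature Extraction with a grid built on mm9. The processed signal is background-subtracted and detrended within the array and not normalised between arrays. The deposited value table of the authors is in log2 units. Its columns equal the log2 processed signal plus a constant per array, minus the median of each probe over the 12 arrays. Its scale, direction and centring by probe were found from the values, and what the constant per array rests on stays unknown. Its column medians were 0.56, -0.0069, 0.75 and 0.32 for IVF embryos 1 to 4 (males 1 and 3), -0.05, -0.72, -1.62 and -0.12 for siCont clones 1 to 4, and 0.01, 0.54, -0.18 and -0.22 for siXist clones 1 to 4. Against scaling to the 75th percentile, the constants shifted the classes by means of -0.354 (IVF), 0.744 (siCont) and -0.390 (siXist) in log2.

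Values were the log2 processed signal minus its 75th percentile over non-control probes of the array. Spots marked as outliers by the scanner software were left out, spots of a probe were averaged, and saturated spots were to be kept but there were 0. A probe was kept when well above background on at least 3 of the 4 arrays of any class (IVF, siCont or siXist), which kept 24857 of 41174 probes. A gene was represented by the kept probe with the highest mean, which left 19052 features, 13540 of them with a gene symbol, and 7 without a value in some group were left out. Accessions in the scanner files were matched without versions to a RefSeq table for GRCm38.p6, which named 26888 probes (65.3%) and 18327 symbols. That table was used for names and chromosomes only, and no coordinates are given because the array grid rests on another build. Of the features, 435 were X-linked, 13098 autosomal and 6 Y-linked.

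All 12 arrays were fitted together in limma 3.58.1 under R 4.3.3 with a mean per group and eBayes (8 residual degrees of freedom), and 6 contrasts were tested two-sided with Benjamini-Hochberg adjustment at 0.05. All-IVF contrasts weight the sexes equally. Gene lists (22, at least 3 tested members) and 20 chromosomes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted within a contrast. Before these tests, 1031 missing values were filled with the group mean. The lists covered the X inactivation centre, the Magea and Xlr clusters, escapees, Y-linked genes, pluripotency, trophectoderm, primitive endoderm, Sertoli, cumulus, sperm, oocyte and 2-cell genes. They also covered paternally and maternally expressed imprinted genes, chromatin enzymes, p53 and apoptosis, unfolded protein and heat stress, interferon response, RNA interference, glycolysis, adhesion and cell cycle. Xist, the X minus autosome value and list medians per embryo were compared by exact two-sided permutation of the difference in means, with 95% intervals from inverting that test. Where a feature was not well above background on 1 or more arrays of the dimmer group, the difference is given as a bound. For it, values on such arrays were raised to -5.60, the highest over arrays of the lowest signal well above background, while tests, ranges over alternatives and figures use values as measured. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

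Groups, contrasts, tests, lists, the alternatives named next and the rule for named genes were fixed before the data were examined. The rule named Xist and Tsix, the 8 genes with the largest change each way and 5 X-linked genes each way among called genes with an official symbol and groups that did not overlap, and up to 3 genes per list. Where fewer passed, those with the smallest p were named as not past the threshold, and the all-IVF contrasts named autosomal genes by it. A gene that the rule named for siCont clones against all IVF embryos is not reported here, and counts over selected genes include it. AK036998 and AK051655, the genes named for the siXist clones against IVF embryos and for female against male embryos were chosen after their values were seen. Alternatives were normexp (offset 50) with quantile normalisation, quantile normalisation alone, the authors' table, no filter or a stricter filter (at least 6 arrays), the mean of probes, array weights, only the groups compared, robust eBayes with a trend, the replicate number as a block, and leaving out each array. Normexp used the median spot signal, since the files hold no mean signal. Leaving out an array was first run with the probes filtered anew each time. After those values had been seen it was changed to keep the genes of the fit to all arrays, except those left with no value in a group. A floor under dim signals (-5.60 in log2), leaving out the lowest-weighted array of each clone group (clone 3 of either), permutation of list medians, the comparison of Xist probes, list tests on the 18392 genes with a value on every array or without Xist, and simulated lists of matched length were added after the data had been examined. Bounds were first set by the lowest signal of each array and only for genes above background on 0 arrays of a group, and were changed after both had been seen. A slide block could not be fitted, since each of 3 slides and 3 scans held 1 class. The procedure was tested on simulated data with genes changed by known folds, and array quality was checked by correlation within classes (0.839 to 0.938) and by array weights.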

Results

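The data comprised 12 single-colour Agilent expression arrays, each hybridised with amplified RNA from 1 mouse embryo at the morula stage, the compact ball of cells that precedes the blastocyst. Embryos came from in vitro fertilisation (IVF, 2 male and 2 female) or from transfer of Sertoli cell nuclei, the supporting cells of the testis, into oocytes. All 8 cloned embryos were male. Of these, 4 had received a control siRNA (siCont clones) and 4 an siRNA against Xist (siXist clones) at 6 to 7 h after activation, and the IVF embryos were not treated. Culture lasted 72 h. Between 50.8% (siCont clone 3) and 61.5% (siXist clone 3) of the 41174 probes on an array were well above background, and the 75th percentile of the processed signal lay between 507 and 1133. Levels below are log2 intensities relative to that percentile, with the SD over embryos, and differences carry the SE of the limma fit to all 12 arrays. The IVF embryos, the siCont clones and the siXist clones each lay on a slide and in a scan of their own, so batch and class cannot be told apart in any comparison between them. The comparison of female with male IVF embryos lay within 1 slide. The number of arrays limits the precision of every value.

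Female and male IVF embryos were compared to give the size of sex-linked differences in normal morulae. Xist, the long non-coding RNA that coats and silences the X chromosome that transcribes it, rose to 5.21 ± 0.05 (n = 2) in female embryos against -5.98 ± 1.5 (n = 2) in male embryos (adjusted p = 0.000138), where 1 of 2 arrays was above background. The Y-linked genes Eif2s3y and Ddx3y, a translation factor subunit and an RNA helicase, were at least 800-fold and at least 591-fold lower in female embryos (adjusted p = 7.41e-05 and 0.000282). Those 3 genes were the whole of the calls among 19052 tested, and each remained called with any 1 of the 12 arrays left out, though the count was 7 without female embryo 2, 6 without female embryo 4 and 5 without siCont clone 3. At an unadjusted p under 0.05 the count was 293, and the groups did not overlap for 28.6% of genes, where chance gives 33.3%. The share of calls that were higher was 33.3% here and 20% after normexp background correction, and the median of all genes was 0.03 here and -0.67 in the authors' table. Of 22 gene lists 4 were called. The X inactivation centre was higher (7 of 8 members, median 1.23, adjusted p = 1.28e-05, and 0.0353 with an estimated correlation), a call that rested on Xist (0.0913 without it), and so were 4 of 4 escapees, genes known to stay active on an inactive X (median 0.78, adjusted p = 0.00257). The Magea and Xlr clusters, multicopy X-linked families expressed mainly in germ cells, were also higher (6 of 10 members, median 2.29, adjusted p = 0.00240). Y-linked genes were lower (5 of 5 members, median -6.17, adjusted p = 3.08e-26, and 0.000254 with an estimated correlation). Over all genes 1 member of the X inactivation centre and 2 Y-linked genes were called, and 1 and 3 adjusted over the list alone, with 0 in either way for the other two lists. The escapee and Magea and Xlr calls were lost with an estimated correlation (adjusted p = 0.0924 and 0.473). The Magea and Xlr call was also lost without female embryo 2 (adjusted p = 0.746) or male embryo 3 (0.383), and that of the escapees without female embryo 4 (0.339). X-linked genes as a set were higher by a median of 0.60 (adjusted p = 8.42e-15, and 0.0901 with an estimated correlation).

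The siXist and siCont clones were compared to ask what the injected siRNA changed in cloned morulae. Xist averaged 4.97 ± 0.48 (n = 4) in siCont clones and 1.93 ± 0.48 (n = 4) in siXist clones. The level left was 12.1% of control, an 8.25-fold difference (95% permutation interval 4.30 to 19.5), and the groups did not overlap (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow). In the fit over all genes the difference of -3.04 ± 0.48 had an adjusted p of 0.11, with a range of 0.0278 to 0.864 over 24 alternatives. It passed with a floor under dim signals (0.0278), without male IVF embryo 1 (0.0481) and without male IVF embryo 3 (0.0480). Xist in siCont clones differed from female IVF embryos by -0.23 (exact permutation p = 0.533, where 4 against 2 arrays cannot give less than 0.0667). Xist in siXist clones stayed at least 146-fold above male IVF embryos (adjusted p = 0.000653). These values come from the brightest of 4 Xist probes, the only 1 whose clone groups did not overlap. Of the other 3, the siXist minus siCont difference as measured was -2.90, 0.04 and 3.97 (exact permutation p = 0.2, 1 and 0.314), so a pair of them showed no fall in the mean. They were above background on only 9, 9 and 8 of the 12 arrays, so these differences rest in part on dim values. For the probe at 0.04, siCont clone 4 lay at -7.60 and the other siCont clones at 1.6 to 2.15, against -1.59 to 2.03 in siXist clones. For that at 3.97, siCont clones 3 and 4 lay at -7.72 and -8.12. With the mean of all Xist probes the siXist minus siCont difference was -0.48 (adjusted p = 0.864). Tsix, the antisense transcript of Xist, was at least 1.63-fold higher (adjusted p = 0.418) and was above background on 1 of 4 siCont arrays.

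**Figure D1:**
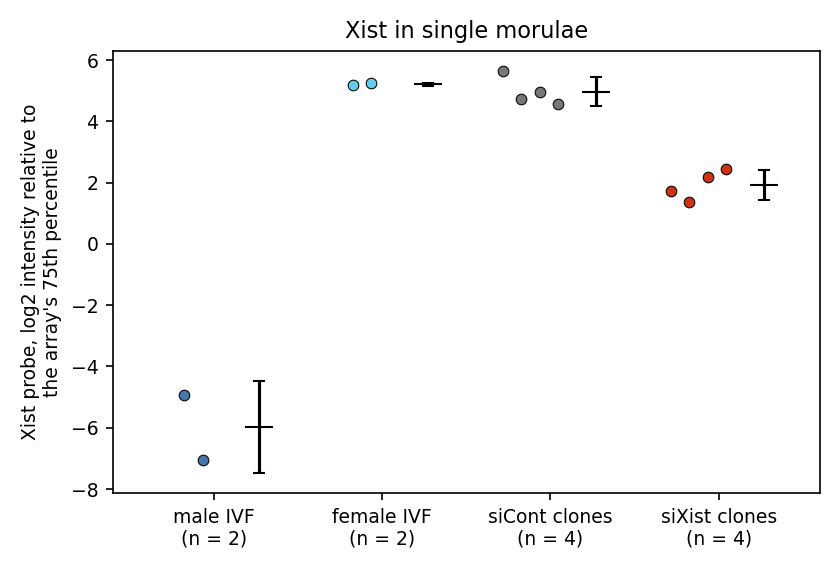
Xist probe in each embryo (1 dot each), as log2 intensity relative to the 75th percentile of its array, with the group mean and SD beside the dots. The siXist clones lie between 1.36 and 2.45, below all siCont clones (4.56 to 5.65) and above both male IVF embryos (-7.04 and -4.92).

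Few genes were called between the siXist and siCont clones, and Xist was not among them (adjusted p = 0.11). The calls were 2 of 19052, both higher in siXist clones and both cDNA features without a gene symbol. AK036998 was at least 27.2-fold higher and AK051655 at least 60.9-fold higher (adjusted p = 0.00178 each), with all 4 siXist arrays and 0 of 4 siCont arrays above background. Both remained called with any 1 array left out and passed in 22 of 24 alternatives, but not after normexp or with the replicate block. They averaged -0.85 and -2.18 in IVF embryos, -7.78 and -8.1 in siCont clones and -0.83 and 0.33 in siXist clones. Both were also called lower in siCont clones than in all IVF embryos (adjusted p = 0.000460 and 0.00680). No gene with a symbol passed here. Those closest to it on the higher side included Yod1, a deubiquitinase (at least 17.8-fold, adjusted p = 0.11), and Btbd3 (at least 20.9-fold on its brightest probe, adjusted p = 0.127), each above background on 1 of 4 siCont arrays. The other kept Btbd3 probe rose by only 1.09 in log2. On the brightest, siCont clone 4 lay at -3.23, against -1.87 to -0.02 in siXist clones. Paqr9, Rbm43 and Zfp266 were above background on 0 of 4 siCont arrays and 4 of 4 siXist arrays, giving bounds of at least 20.8-fold, 5.5-fold and 2.84-fold, with adjusted p from 0.11 to 0.178. Evi5l, above background on the same arrays, was at least 8.08-fold higher (adjusted p = 0.11). On the lower side, Echdc3 differed by -2.79 ± 0.47, Abhd18 by -3.15 ± 0.53 and Rras2, a small GTPase, by -2.08 ± 0.37 (adjusted p from 0.124 to 0.134). The value of Rras2 is that of its brightest probe, and its other kept probes fell less, by -0.43 and -0.49. Ptx3, a pentraxin that cumulus cells secrete into their matrix, was at least 2.15-fold lower (adjusted p = 0.134, n = 3 and 4), with 0 of the 3 siXist values above background. Over 24 alternatives Zfp266 passed in 4, Paqr9 (adjusted p down to 8.78e-05) and Rbm43 in 3 each, Yod1 in 2, and Btbd3 (0.00311), Evi5l and Echdc3 in 1 each. Of the 435 X-linked genes tested 0 were called, and 16 were higher and 32 lower at an unadjusted p under 0.05. The X-linked genes with the smallest p besides Xist were Mageb4, Syp, Efhc2 and Zfp449 on the higher side (at least 13.2-fold, 2.98-fold, 22.5-fold and 11-fold), above background on 1, 1, 1 and 0 of 4 siCont arrays. On the lower side they were Atrx, a chromatin remodeller (-2.26 ± 0.53), and Tmem255a (-1.88 ± 0.46), all with adjusted p from 0.242 to 0.261. Of these 6, only Mageb4 passed in any of the alternatives (2 of 24, 0.0168 and 0.0423).

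No gene list was called in a single direction between the siXist and siCont clones by camera in limma with either correlation or by fry, and 4 of 22 had an unadjusted p under 0.05. A fry test for changes in either direction passed for the X inactivation centre (adjusted p = 0.000564), which includes the siRNA target Xist, but not without Xist (0.0759). It also passed for the trophectoderm (0.000384) and cumulus lists (0.0406) with missing values filled by the group mean, but not with only the genes that had every value (0.549 and 0.636). All 7 measured genes of the 2-cell list, transcribed at the onset of embryonic transcription, were lower (median -1.54, adjusted p = 0.0720). They included Zscan4c (at least 1.98-fold) and Tcstv3 (at least 12.2-fold), above background on 2 and 3 of 4 siXist arrays, with 0 members called over all genes and 1 adjusted over the list alone. Cell cycle genes were lower for 23 of 27 (median -0.45, adjusted p = 0.0720), with Cdk2 at -2.26 ± 0.67, Mad2l1 at -1.14 ± 0.48 (n = 2 and 4) and Ccne1 at -0.86 ± 0.36. In the authors' table, where the median of all genes was 0.93, the cell cycle median turned to 0.68, Mad2l1 to 0.27 and Ccne1 to 0.28. Of the X inactivation centre 7 of 8 genes were lower (median -1.41, adjusted p = 0.114), among them Xist itself and Chic1 (-2.19 ± 0.66), with 2 adjusted over the list alone. Without Xist its adjusted p was 0.638. The test with Xist passed after normexp (0.0186) and with a floor under dim signals (0.0339), with a range up to 0.994 over 19 alternatives. Sperm and spermatid genes were lower for 4 of 6 (median -0.98, adjusted p = 0.198), with Prm2, a protamine, at -1.24 ± 0.44, and their median turned to 0.15 in the authors' table. The Magea and Xlr list had a median of -0.30 and a mean of -0.18 while its test pointed up (adjusted p = 0.992), and its median turned to 0.16 under quantile scaling and 0.83 in the authors' table. Glycolysis genes had a median of 0.15, a mean of -0.05 and a test pointing up (adjusted p = 0.862), although Hk2, a hexokinase, was at -1.24 ± 0.32. The 2-cell list passed after normexp (adjusted p = 0.0186), with the floor (0.0283), without siCont clone 4 (0.00307) and without siXist clone 4 (0.0205). The cell cycle list passed with the floor (0.0283), without siCont clone 4 (0.0313) and without siXist clone 2 (0.0229).

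At an unadjusted p under 0.05, 2646 genes differed between the siXist and siCont clones against 953 expected, 836 higher and 1810 lower, and groups did not overlap for 8.04% of genes, where chance gives 2.86%. In simulated data of this design limma recovered 26.5% of genes changed 4-fold and 64% of those changed 16-fold. Genes changed by smaller and by larger folds were planted in the same data sets. Many planted changes ease the adjusted threshold for one another, whereas few genes were called in the real comparison. These shares therefore cannot give the recovery of a lone change in the real data, which may be lower. The median of all genes was -0.21 here, -0.06 after normexp and 0.93 in the authors' table, where 3866 were higher and 77 lower without adjustment. The count called was 8 to 56 with any 1 of the 12 arrays left out (56 without siXist clone 1), 0 after normexp and 19 in the authors' table.

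To ask whether the knockdown moved X-linked genes as a whole, the median of X-linked genes minus that of autosomal genes was taken in each embryo. It was -0.76 ± 0.36 (n = 4) in siCont clones, -0.72 ± 0.27 (n = 4) in siXist clones, -0.56 ± 0.03 (n = 2) in male IVF embryos and 0.20 ± 0.06 (n = 2) in female IVF embryos. The siXist minus siCont difference was 0.04 ± 0.22 (SE, 95% permutation interval -0.81 to 0.57, exact permutation p = 0.914), which was smaller than the spread between embryos. It was -0.06 without siCont clone 1, -0.05 without siCont clone 3, -0.06 without siXist clone 3 and -0.01 without siXist clone 4, and 0.20 without siCont clone 4 or 0.16 without siXist clone 2. The siCont clones differed from male IVF embryos by -0.20 ± 0.18 (exact permutation p = 0.467) and the siXist clones by -0.16 ± 0.14 (exact permutation p = 0.6), in a design whose smallest p is 0.0667. Without siCont clone 1 or 3 the first value was -0.10 or -0.11, without clone 4 it was -0.36, and without male IVF embryo 3 it was -0.31 (-0.22 with no gene dropped). Without siXist clone 2 the second was -0.04, without clone 3 it was -0.27, and without male IVF embryo 3 it was -0.26 (-0.24 and -0.18 with no gene dropped). Leaving out male IVF embryo 3 dropped 160 genes, 7 of them X-linked, that had no value in male IVF embryo 1. All 8 clones together lay at -0.945 from female IVF embryos (exact permutation p = 0.0222, the smallest possible), and at -0.178 from male IVF embryos (exact permutation p = 0.422). Chromosome X was not called as a set between siXist and siCont clones (adjusted p = 0.933), nor was any of the other 19 chromosomes.

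**Figure D2:**
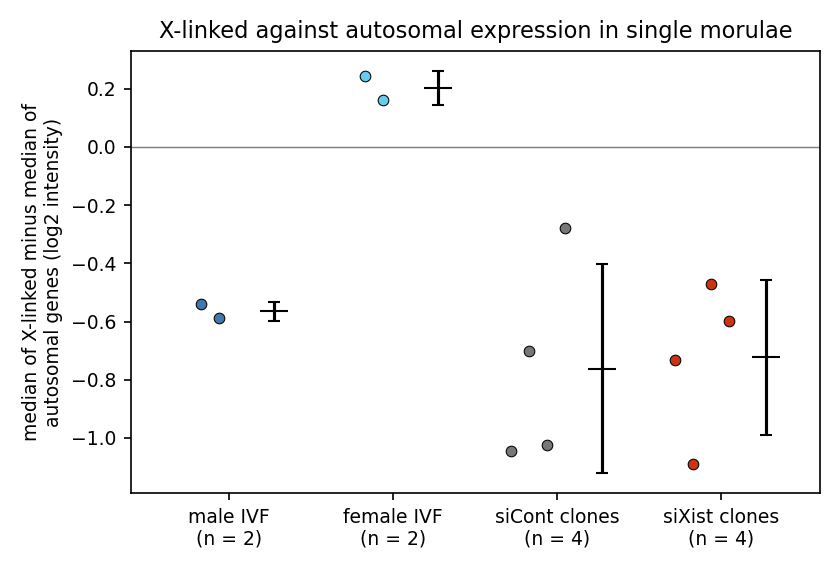
Median log2 intensity of 435 X-linked genes minus that of 13098 autosomal genes in each embryo (1 dot each), with the group mean and SD beside the dots. Embryos within each clone group spread from -1.05 to -0.28 (siCont) and from -1.09 to -0.47 (siXist), around the male IVF embryos (-0.59 and -0.54) and below both female IVF embryos (0.16 and 0.24).

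The siCont clones were set against male IVF embryos to ask which genes differ in cloned embryos of the same sex. Xist was at least 1202-fold higher (adjusted p = 4.19e-05, in log2 from 7.42 to 12.01 over 24 alternatives as measured). Rhox5, an X-linked homeobox gene, was at least 463-fold higher (adjusted p = 0.0351, from 7.19 to 12.74), and 1 of 2 male IVF arrays was above background for either gene. The call of Rhox5 was lost with 8 of the 12 arrays left out in turn, among them male IVF embryo 3 (0.177). Atg10, an enzyme of autophagosome formation, was at least 266-fold higher on its brightest probe (adjusted p = 0.0133, from 5.74 to 10.39). On that probe 0 of 2 male IVF arrays were above background, and the other kept Atg10 probe rose by only 3.85 in log2, so the bound does not hold for both. The call of Atg10 was lost without either male IVF embryo (0.147 and 0.0953). The X-linked Tceal8 rose 47.3-fold (5.56 ± 0.71, adjusted p = 0.0226). Female IVF embryos lay near the clones for both X-linked genes. Rhox5 was at 5.43 and 5.09 in females and 2.58 to 6.23 in siCont clones, and Tceal8 at 0.77 and 0.15 against 0.53 to 2.88. Myom3, a muscle M-band protein, rose 28.9-fold (adjusted p = 0.0193). Meioc, which is needed for meiotic prophase, rose at least 118-fold (adjusted p = 0.00399) and Plxdc2, a membrane protein, at least 63.4-fold (adjusted p = 0.0247). On the other side, Xlr5c fell at least 36.2-fold (adjusted p = 2.12e-05) and C8b, a complement component, at least 30.3-fold (adjusted p = 0.0193). Gml2 fell at least 28.3-fold (adjusted p = 0.00626), the keratin Krt27 at least 8.87-fold (adjusted p = 0.0287) and Ccdc172 at least 41.7-fold (adjusted p = 0.0193, 1 of 4 siCont arrays above background). Xlr5a (at least 169-fold lower, adjusted p = 0.0610) and Isl1, a LIM homeobox gene (at least 24.2-fold lower, adjusted p = 0.0581), each above background on 1 of 4 siCont arrays, did not pass, nor did Evi5l (at least 18.6-fold lower, adjusted p = 0.0527). The same held for the X-linked Bex1 (at least 67.7-fold higher, 1 of 2 male IVF arrays above background) and Bex2 (at least 28.3-fold higher). It also held for Magea8, Magea1 and Tceal1 (at least 17.6-fold, 23.2-fold and 4.36-fold lower), with adjusted p from 0.0804 to 0.146 for these 5. Over 24 alternatives, or 23 for some, Xlr5a passed in 8 (adjusted p down to 0.00147), Isl1 in 6 (0.000285), Evi5l in 6 (0.0160), Bex2 in 4, Magea8, Magea1 and Tceal1 in 3 each, and Bex1 in 2. Rlim, an X-linked ubiquitin ligase that promotes Xist transcription, was at -2.42 ± 0.87 (adjusted p = 0.451) on its brightest probe. Its other kept probes showed larger falls, of -4.85 and -5.70.

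In gene groups, all 10 measured Magea and Xlr genes were lower in siCont clones than in male IVF embryos (median -5.78, adjusted p = 1.96e-13, and adjusted p = 0.0634 with an estimated correlation). Of them 1 was called over all genes and 7 adjusted over the list alone. Glycolysis genes were higher for 18 of 20 (median 1.15, adjusted p = 2.05e-05, and adjusted p = 0.126 with an estimated correlation), 0 called over all genes and 4 adjusted over the list alone. The p53 and apoptosis list was higher for 17 of 18 (median 0.85, adjusted p = 0.00138, and 0.5 with an estimated correlation). Oocyte genes were higher for 15 of 22 (median 0.97, adjusted p = 0.0125, and 0.250 with an estimated correlation). Pluripotency genes were lower for 16 of 19 (median -0.70, adjusted p = 0.0123, and 0.5 with an estimated correlation). These last 3 lists had 0 members called, either over all genes or adjusted over the list alone. In the authors' table, where the median of all genes was -1.47, the glycolysis, p53 and oocyte medians turned to -0.29, -0.60 and -0.48, which were 1.17, 0.87 and 0.99 above that median. The pluripotency call was lost without siCont clone 2 (adjusted p = 0.0706), and the oocyte call without it (0.0706) or male IVF embryo 1 (0.0591).

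In this comparison limma called 18 genes, 9 higher and 9 lower, with 3 X-linked genes among the higher and 1 among the lower, against 1769 at an unadjusted p under 0.05. Groups did not overlap for 22.0% of genes, where chance gives 13.3%. The share of calls that were higher was 50% here, 22.7% after normexp and 12.2% in the authors' table. The count was 10 without male IVF embryo 1, 6 without male IVF embryo 3, 11 without siCont clone 2, and 36 without female IVF embryo 2 or 4. Among 12 called genes with a symbol, Xist and Xlr5c stayed called whichever array was left out. Of these 12, 7 were lost without male IVF embryo 1 (adjusted p from 0.141 to 0.231) and 10 without male IVF embryo 3 (0.0597 to 0.216). Without siCont clones 2, 3 and 4, 6, 4 and 3 were lost, and 1 without siCont clone 1 or any 1 siXist clone (adjusted p from 0.0503 to 0.0868).

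With all 4 IVF embryos as reference, sexes weighted equally, the siCont clones were compared for autosomal genes and for the lists. Meioc rose at least 118-fold and Plxdc2 at least 63.4-fold (adjusted p = 0.000702 and 0.00541). Bhlhe40, a circadian and hypoxia-responsive repressor, rose 89.4-fold and the cytochrome P450 Cyp2j6 at least 21.1-fold. F2r, the thrombin receptor, rose 67.5-fold, Atg10 at least 32.1-fold and Ppp1r36 at least 25.1-fold (adjusted p from 0.0185 to 0.0396 for these 5). Cyp2j6 was above background on 1 of 4 IVF arrays. On its brightest probe Atg10 lay at -7.89 and -6.83, not above background, in male but 0.32 and 0.68 in female IVF embryos. The males thus carried most of the difference on that probe, and the other kept Atg10 probe rose by 3.45 in log2. The T-box gene Tbx18 fell at least 71.6-fold, Gml2 at least 22.6-fold and C8b at least 19.8-fold (adjusted p = 0.0169, 0.00154 and 0.00541). Tmem158 fell at least 139-fold, Isl1 at least 22.4-fold, Lin28b, which binds precursors of let-7 microRNAs, at least 80.2-fold, Wfdc15a at least 55.8-fold, and the homeobox gene Gsc at least 38.1-fold (adjusted p from 0.0133 to 0.0465). Those 5 were above background on 2, 1, 3, 2 and 2 of 4 siCont arrays.

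All 10 measured genes of the Magea and Xlr clusters were lower in siCont clones than in IVF embryos (median -6.87, adjusted p = 6.34e-16, and 0.0366 with an estimated correlation), 6 called over all genes and 9 adjusted over the list alone. Magea8 fell at least 61.6-fold, Magea6 at least 41.5-fold and Xlr5c at least 26.8-fold (adjusted p = 0.00680, 0.0124 and 5.10e-06). Glycolysis genes were higher for 18 of 20 (median 1.30, adjusted p = 1.66e-06, and adjusted p = 0.0514 with an estimated correlation), 3 called over all genes and 6 adjusted over the list alone. Those called were Ldha, lactate dehydrogenase A (4.44 ± 0.69, adjusted p = 0.0343), Pfkl, a phosphofructokinase (at least 8.61-fold, adjusted p = 0.0157, 3 of 4 IVF arrays above background), and Tpi1, triosephosphate isomerase (2.60 ± 0.44, adjusted p = 0.0421). The Y-linked list was higher (median 3.78, adjusted p = 2.08e-05, and 0.0366 with an estimated correlation), with Eif2s3y (at least 33.1-fold), Ddx3y (at least 16.9-fold) and Kdm5d (at least 6.31-fold) called, and 2 of the 4 IVF embryos were female, the 2 whose arrays were not above background for them. Chromosome X was lower as a set (median -0.41, adjusted p = 0.00475, and 0.931 with an estimated correlation) against the same mixed reference, and 0 chromosomes were called without female IVF embryo 2 or siCont clone 1.

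The p53 and apoptosis list was higher for 17 of 18 genes (median 0.96, adjusted p = 6.00e-05, and adjusted p = 0.338 with an estimated correlation), 0 called over all genes and 1 adjusted over the list alone. Pmaip1, the BH3-only protein Noxa, was at 2.70 ± 0.64 (adjusted p = 0.121), Phlda3 at 1.55 ± 0.46 (0.205) and Apaf1, the apoptosome scaffold, at 1.70 ± 0.58 (0.261). The other kept Apaf1 probes were at 1.08 and, in the other direction, -0.65. Pluripotency genes were lower for 17 of 19 (median -0.88, adjusted p = 0.00593, and 0.362 with an estimated correlation). Utf1 was at -1.56 ± 0.49 (adjusted p = 0.228), Tfcp2l1 at -1.34 ± 0.47 (0.267) and Zfp42, also called Rex1, at -0.90 ± 0.35 (0.310). Oocyte genes were higher for 15 of 22 (median 0.64, adjusted p = 0.0217, and 0.255 with an estimated correlation), with Oog1 at 1.64 ± 0.42 (adjusted p = 0.145), Oosp1 at 1.48 ± 0.43 (0.204) and the nuclear chaperone Npm2 at 1.59 ± 0.51 (0.231). In both lists 0 members were called, over all genes or adjusted over the list alone. In the authors' table, where the median of all genes was -1.13, the p53 and oocyte medians turned to -0.14 and -0.46, which were 0.99 and 0.68 above it. The pluripotency call was lost without siCont clone 2 (adjusted p = 0.0543). That of the oocyte list was lost without female IVF embryo 2 (0.118), siCont clone 1 (0.0757) or siCont clone 2 (0.11).

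Against all IVF embryos limma called 79 genes in siCont clones, 43 higher and 36 lower, with 8 X-linked genes of which 7 were lower, and 2584 at an unadjusted p under 0.05. Groups did not overlap for 10.3% of genes, where chance gives 2.86%. The share of calls that were higher was 54.4% here, 43.6% after normexp and 12.8% in the authors' table. The count was 35 without male IVF embryo 1, 33 without male IVF embryo 3, and 42, 50 and 46 without siCont clones 2, 3 and 4. Of 25 called genes that the rule selected in this comparison, 9 stayed called whichever array was left out, namely Meioc, Plxdc2, C8b, Gml2, Xlr5c, Magea8, Magea6, Eif2s3y and Ddx3y. The other 16 were lost without at least 1 array, 15 of them without male IVF embryo 1 (adjusted p from 0.0541 to 0.138) and 13 without male IVF embryo 3 (0.0599 to 0.175). Without female IVF embryos 4 and 2, 12 and 6 were lost, without siCont clones 1 to 4, 5, 9, 11 and 11, and without siXist clones 1 to 4, 3, 4, 5 and 2 (adjusted p from 0.0501 to 0.121).

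The siXist clones were compared with the IVF embryos to ask what still differed after the knockdown. Against male IVF embryos, Xist was at least 146-fold higher (in log2 from 5.55 to 8.97 over 24 alternatives as measured) and Rhox5 at least 1606-fold (from 8.99 to 14.54), with 1 of 2 male IVF arrays above background for either. Atg10 was at least 93.4-fold higher on its brightest probe (from 4.36 to 8.86). Its other kept probe, with the smaller rise in siCont clones, was lower still in siXist than in siCont clones (-1.04 in log2). Tceal8 rose 73.5-fold, Meioc at least 67.3-fold and Plxdc2 at least 58.3-fold (adjusted p from 0.000653 to 0.0288 for these 6). Rhox5 lay at 5.68 to 7.24 in siXist clones and at 5.43 and 5.09 in female IVF embryos, and Tceal8 at 1.23 to 3.06 against 0.77 and 0.15. Ccdc172 fell at least 44.1-fold, Xlr5c at least 36.2-fold, Gml2 at least 28.3-fold, Isl1 at least 27.1-fold and Krt27 at least 8.87-fold (adjusted p from 9.12e-06 to 0.0426). C8b fell at least 28.7-fold (adjusted p = 0.0216), with 1 of 4 siXist arrays above background. The Magea and Xlr list was lower for 10 of 10 (median -6.58, adjusted p = 3.54e-13, and 0.0650 with an estimated correlation), 1 called over all genes and 9 adjusted over the list alone. Glycolysis genes were higher for 14 of 20 (median 1.36, adjusted p = 6.39e-07, and 0.0650 with an estimated correlation), 0 called over all genes and 7 adjusted over the list alone. The p53 list (13 of 18 higher, median 0.41, adjusted p = 0.0114) and the oocyte list (14 of 22 higher, median 0.43, adjusted p = 0.0303) were lost with an estimated correlation (adjusted p = 0.784 and 0.330). Adjusted over the list alone, 0 of the p53 and 1 of the oocyte genes passed. The p53 call was lost without male IVF embryo 3 (adjusted p = 0.178), siXist clone 3 (0.194) or siXist clone 4 (0.0875), and the oocyte call without male IVF embryo 1 (0.149), siXist clone 1 (0.107) or siXist clone 4 (0.0516).

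In this comparison limma called 21 genes, 9 higher and 12 lower, and 1590 had an unadjusted p under 0.05, while groups did not overlap for 23.1% of genes, where chance gives 13.3%. The median of all genes was -0.22, -0.02 after normexp and -0.54 in the authors' table, and the share of calls that were higher was 42.9% here and 27.3% after normexp. The count was 10 without male IVF embryo 1, 6 without male IVF embryo 3, 56 without female IVF embryo 2 or 4, 34 without siXist clone 1 and 33 without siXist clone 4. Xist and Xlr5c stayed called whichever array was left out, and of 12 named genes 8 were lost without male IVF embryo 1 (adjusted p from 0.0706 to 0.382) and 10 without male IVF embryo 3 (0.0525 to 0.251). Without siXist clones 2 and 3, 2 each were lost, and 1 each without siXist clones 1 and 4 and siCont clones 2, 3 and 4 (adjusted p from 0.0501 to 0.0902).

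Against all IVF embryos, the Magea and Xlr genes were lower in siXist clones for 10 of 10 (median -7.20, adjusted p = 1.69e-14, and 0.0253 with an estimated correlation), 7 called over all genes and 9 adjusted over the list alone. Magea8 fell at least 61.6-fold and Xlr5c at least 26.8-fold, and Magea6 fell at least 36.2-fold with 2 of 4 siXist arrays above background (adjusted p = 0.00770, 2.08e-06 and 0.0256). Glycolysis genes were higher for 14 of 20 (median 1.48, adjusted p = 1.56e-07, and 0.0364 with an estimated correlation, or 0.0512 with only the genes that had a value on every array), 3 called over all genes, and 9 higher and 1 lower adjusted over the list alone. The called genes were Pfkl (at least 13-fold), Tpi1 (3.16 ± 0.44) and Ldha (4.24 ± 0.69), with adjusted p of 0.00770, 0.0192 and 0.0314. Meioc rose at least 67.3-fold and Plxdc2 at least 58.3-fold, while Gml2 fell at least 22.6-fold, Wfdc15a at least 181-fold, Tbx18 at least 44.1-fold and Gsc at least 42.8-fold (adjusted p from 0.00135 to 0.0256). Wfdc15a, Tbx18 and Gsc were above background on 2, 1 and 2 of 4 siXist arrays. Bhlhe40 (4.47 ± 1.07), F2r (3.94 ± 0.98), Tmem158 (-3.24 ± 1.04) and Lin28b (-4.63 ± 0.96) did not pass in siXist clones (adjusted p from 0.0758 to 0.222), and none of them was called between the clone groups. The p53 list was higher for 13 of 18 (median 0.71, adjusted p = 0.000877, and 0.537 with an estimated correlation), with 0 members called over all genes or adjusted over the list alone. The Y-linked list was higher for 5 of 5 (median 2.74, adjusted p = 2.83e-08, and 0.0171 with an estimated correlation), again with 2 female embryos in the reference. Chromosome X was lower as a set (median -0.57, adjusted p = 0.0154, and 0.994 with an estimated correlation), and 0 chromosomes were called without female IVF embryo 2 or siXist clone 2.

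Here limma called 110 genes, 54 higher and 56 lower, and 2646 at an unadjusted p under 0.05, while groups did not overlap for 13.1% of genes, where chance gives 2.86%. The share of calls that were higher was 49.1% here and 60.4% under quantile scaling, and the median of all genes was -0.23, against -0.04 after normexp. The count was 37 without male IVF embryo 1, 52 without male IVF embryo 3, 56 without siXist clone 2 and 34 without siXist clone 3. Xlr5c, Magea8, Meioc, Plxdc2, Gml2, Pfkl and Wfdc15a stayed called whichever array was left out. Of 12 named genes 5 were lost without male IVF embryo 1, siXist clone 2 or siXist clone 3, 3 without female IVF embryo 2, male IVF embryo 3 or siXist clone 1, 2 without female IVF embryo 4, and 1 without siCont clone 4 or siXist clone 4 (adjusted p from 0.0504 to 0.106).

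**Figure D3:**
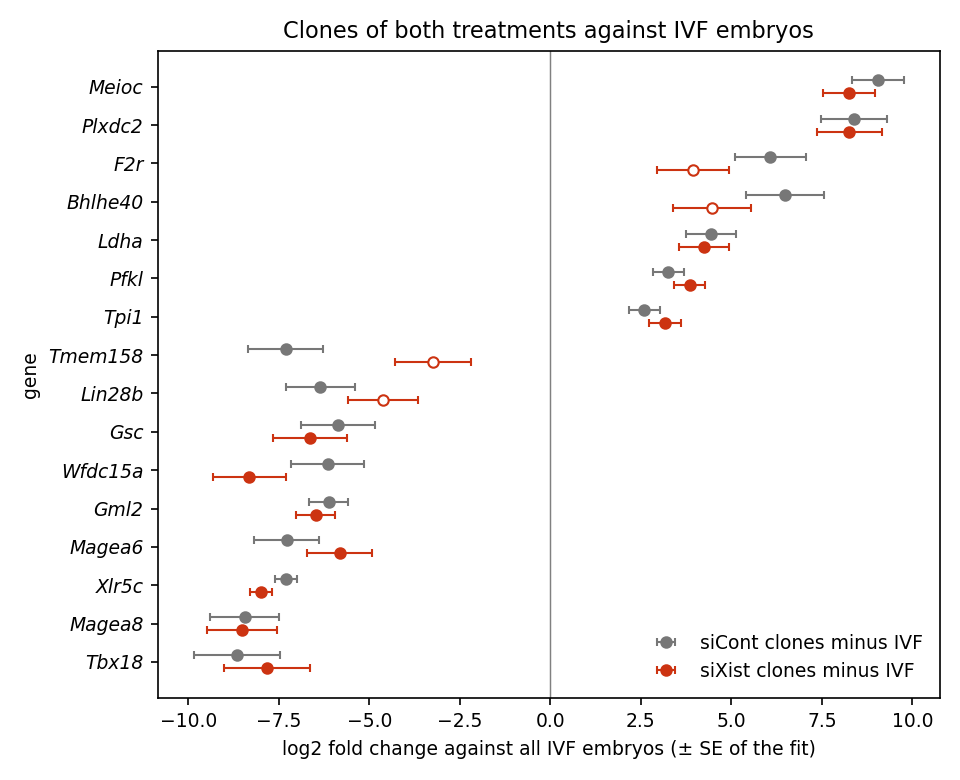
Log2 fold change against all IVF embryos with its SE for 16 genes in siCont clones (grey, n = 4) and siXist clones (red, n = 4), with filled dots for an adjusted p under 0.05 and open dots otherwise. Xlr5c lies at -7.30 and -7.99 and Ldha at 4.44 and 4.24, and values of genes not well above background in a group are shown as measured.

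The level of the Magea and Xlr and of the glycolysis genes was also taken per embryo, as the median over the list, in a test chosen after the data had been examined. The Magea and Xlr median lay between -7.53 and -6.64 in siCont clones, between -7.95 and -5.10 in siXist clones and between -2.23 and 2.43 in IVF embryos. It differed from IVF embryos by -7.27 in siCont clones and by -6.52 in siXist clones, with an exact permutation p of 0.0286 in either case, the smallest possible and 0.157 adjusted over the 22 lists. All siCont medians lay under the floor of -5.60, so the sizes of these differences rest on dim values as measured. The siXist minus siCont difference was 0.75 (95% permutation interval -1.31 to 2.43, exact permutation p = 0.286). The glycolysis median was 1.51 higher in siXist clones than in IVF embryos (exact permutation p = 0.0286, adjusted 0.157) and 1.22 higher in siCont clones (exact permutation p = 0.0571, adjusted 0.210).

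**Figure D4:**
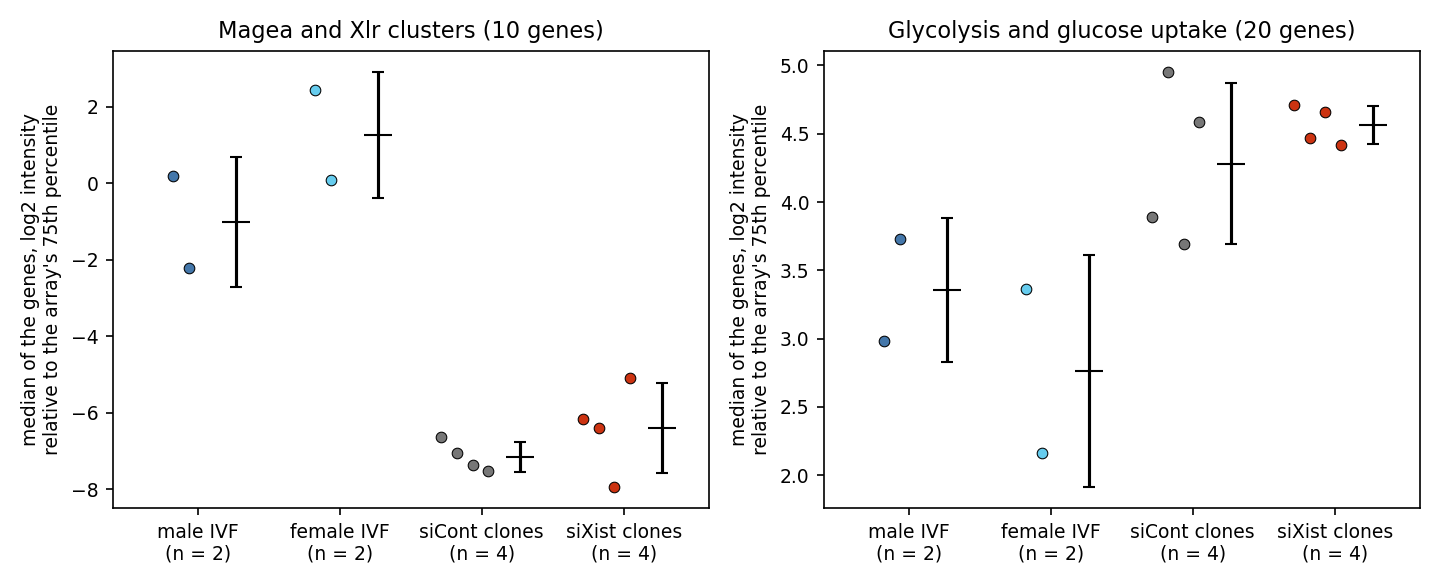
Median log2 intensity, relative to the 75th percentile of the array, of 10 Magea and Xlr genes (left) and 20 glycolysis genes (right) in each embryo (1 dot each), with the group mean and SD beside the dots. All 8 clones lie at or below -5.10 for Magea and Xlr genes, and all 4 IVF embryos at or above -2.23. For glycolysis genes the siXist clones lie between 4.42 and 4.71, above all IVF embryos.

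The differences of the 2 clone groups from IVF embryos were compared with each other. Of the genes called against all IVF embryos, 24 were higher and 19 lower in both groups, where independent lists would share 0.122 and 0.106. Both groups were set against the same IVF arrays, which inflates such a count. In 20 simulations of unchanged groups against shared controls, 0 genes were shared at that threshold, since almost none passed. Lists as long as the real ones, taken by the smallest p in each simulation, shared 8.05 higher (3 to 13) and 6.6 lower genes (2 to 10). At an unadjusted p under 0.05, 406 higher and 542 lower genes were shared, and simulated lists of that length shared 328 (311 to 345) and 466 (422 to 490). With 2 IVF embryos as reference for siCont clones and the other 2 for siXist clones, 2 higher and 4.25 lower genes were shared on average over 4 ways, where independent lists would share 0.00266 and 0.00710. Without adjustment these were 190 and 255 genes, 4.96 and 4.44 times the number for independent lists. All IVF embryos lay on 1 slide, so both parts of a split carry any effect of that slide. No unchanged groups were simulated for the split, and with shared controls such groups shared 9.61 and 9.68 times the number for independent lists. The split therefore cannot decide how much of the sharing comes from the clones. Against male IVF embryos, 7 higher genes were shared out of 9 and 9, and 8 lower genes out of 9 and 12.

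Whether genes lower in siCont clones than in IVF embryos were higher in siXist than in siCont clones was measured with the siCont clones split 2 and 2, so that genes were chosen and measured on different embryos. The siCont clones shared a slide, so both parts of a split carry any effect of that slide, and it cannot be told apart from recovery. On average over 6 splits 48.1% of such genes were higher in siXist clones (42.4% to 54.1%), against 40.2% of all genes, an excess of 7.90 points (3.89 to 12.3), and 5.06 points after normexp. Simulated unchanged groups gave 50.3%, but they carry no shift of all genes, whose median was -0.23 in the real data. The real and simulated shares thus have unlike baselines and cannot be set side by side, with the split or without it. Without the split the share was 70.9%, where simulated unchanged groups gave 87.4%, and with male IVF embryos alone as reference it was 55.4%, an excess of 15.2 points. Genes entered at an unadjusted p under 0.05, a threshold set once the data were available.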

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

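The values below are those of single embryos set far apart from the other three of their group, by the gap to the nearest of them over the range of the group (above 0.83). The rule was fixed beforehand, and which genes and lists it was applied to followed in part from values already seen. It was met in 23 of 249 groups of 4 embryos, where chance gives about 1 in 20, or 12.5. No explanation was tested for any of them.

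Among quality measures, siCont clone 3 had a mean correlation with its group of 0.847 (others 0.862 to 0.863) and an array weight of 0.403 (others 0.843 to 0.932). Among genes, siCont clone 1 stood apart for Cubn (2.44), F2r (2.85) and Phlda3 (2.02). In siCont clone 2 these were Tfap2a (-4.57) and Yod1 (-5.40), in siCont clone 3 Magea6 (-6.11) and Mageb4 (-2.58), and in siCont clone 4 Btbd3 (-3.23, others -8.54 to -7.87) and Ntn3 (-2.66). In siXist clone 2 they were C8b (-5.29) and Tsix (-5.23), and in siXist clone 3 Krt27 (-8.83), Ldha (5.47, others 4.29 to 4.31) and Ntn3 (-7.02). In siXist clone 4 they were AK051655 (-0.0901), Magea1 (-4.50) and Tbx18 (-2.80, others -9.01 to -8.52). Among lists, the pluripotency median was 3.56 in siXist clone 3 (others 4.38 to 4.47) and the oocyte median -2.58 in siXist clone 4 (others -1.20 to -1.15). The escapee median was 1.91 in siCont clone 2 (others 2.77 to 2.84), and that of maternally expressed imprinted genes -0.55 in siCont clone 3 (others 1.31 to 1.52).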

How the results depend on the processing

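The floor under dim signals and leaving out the lowest-weighted array of each clone group were chosen after the data had been examined, as were many of the genes and lists followed here. Of 1563 alternative values for called genes, 1212 kept direction and call and 351 kept the direction alone. For genes not called, 1691 of 1767 stayed so in the same direction, 73 passed and 3 reversed. For called lists, over 19 alternatives, the numbers were 387 and 50 of 437, and for other lists 382 of 418, with 14 passing and 22 reversed. Outside these 19, the medians of 5 of 23 called and 13 of 22 other lists reversed in the authors' table, and 0 and 2 under quantile scaling. The list test, which sets members against all other genes, still passed in the same direction for 22 of the 23 called lists under either scaling. Of the 22 other lists it passed for 5 in the authors' table and 0 under quantile scaling. The authors' table differs by a constant per array and a centring per probe. Such a constant moves members and other genes alike, so the agreement of called lists there was largely fixed in advance. Of 440 alternative values of the comparisons themselves, 331 stayed close, 104 moved and 5 reversed. The cause was not tested. The slide block could not be fitted, since each slide held 1 class. Signal over background limits folds of dim genes to bounds. The replicate number does not pair embryos (same-number correlations -0.153 to 0.0642).

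Counts of called genes, in the order siXist vs siCont, siCont vs male IVF, siCont vs all IVF, siXist vs male IVF, siXist vs all IVF and female vs male where they moved, were as follows, after the calls shared with the fit reported above. Of 2, 18, 79, 21, 110 and 3 calls, 0, 9, 48, 9, 66 and 3 were kept with normexp and 2, 14, 49, 9, 41 and 3 in the authors' table. The replicate block kept 0, 2, 11, 2, 13 and 2, the floor 2, 16, 64, 16, 84 and 3, and the fit without the lowest-weighted arrays 2, 11, 23, 12, 33 and 3. Normexp gave 0 for the first and 5 for the last. The authors' table gave 19, 41, 10 (siXist vs male IVF) and 42 (siXist vs all IVF). No filter gave 39 and 67 against male IVF embryos (siCont, siXist) and 23 for female vs male, and the stricter filter 7, 8, 53 (siXist vs all IVF) and 5 (female vs male). Array weights gave 79 and 204 against male IVF embryos, 254 for siXist vs all IVF and 8 for female vs male. With only the groups compared, counts were 12, 83, 76 (siXist vs male IVF) and 0 (female vs male), from fewer arrays. The replicate block gave 0, 2, 12, 2 and 13 for the first 5 comparisons. The floor gave 4, 29 and, for female vs male, 6. Without the lowest-weighted arrays (clone 3 of either group) counts were 15, 43 (siCont vs all IVF) and 56 (siXist vs all IVF). With 1 array left out, counts ranged from 8 to 56, 6 to 36, 33 to 106, 6 to 56, 34 to 127 and 3 to 7. With the probes filtered anew they ranged from 8 to 56, 6 to 32, 31 to 107, 5 to 48, 35 to 129 and 3 to 6.

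Counts of called lists with an estimated correlation were 0, 2, 0 and 2 for siCont vs male IVF, siCont vs all IVF, siXist vs male IVF and female vs male, and with fry 3, 3, 2 and 2. For siXist vs siCont they were 2 with normexp and 3 with the floor. With only genes that had a value on every array, all called lists were kept and the oocyte list passed for siXist vs all IVF (adjusted p = 0.0416). With 1 array left out, lists ranged from 0 to 2, 3 to 8, 4 to 8, 2 to 4, 4 to 6 and 3 to 4. Called chromosomes were 0 with an estimated correlation in both all-IVF comparisons and female vs male, with fry 0, 2 and 0, and 0 with no filter in both all-IVF comparisons. Without the lowest-weighted arrays they were 1, 1 and 2 for the siXist comparisons (siCont, male IVF, all IVF), and with 1 array left out 0 to 1, 0, 0 to 2, 0 to 1, 0 to 2 and 1. The recovered share was 70.9% without the split, which reuses the siCont arrays, and 55.4% with male IVF embryos alone.

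Reversals were as follows, apart from those of lists in the authors' table and under quantile scaling, which are given beside each list. For siXist vs siCont clones, the authors' table gave 0.44 for Xlr5c, 0.28 for Ccne1 and 0.27 for Mad2l1, and the replicate block gave -0.048 for glycolysis. Glycolysis ranged from -0.10 to -0.0067 without siCont clone 1, siCont clone 4 or siXist clone 3. Magea and Xlr genes, from -0.62 without siXist clone 4, were at 0.14 without siCont clone 4, 0.34 without siXist clone 3 and 0.049 without the lowest-weighted arrays. X minus autosome was -0.16 without the lowest-weighted arrays and -0.059 to -0.0073 without siCont clone 1 or 3 or siXist clone 3 or 4, with a whole range of -0.059 to 0.20. The ranges against male IVF embryos were -0.36 to -0.10 (siCont) and -0.27 to -0.04 (siXist). With the probes filtered anew the 3 ranges were 0.0040 to 0.26, with no reversal, -0.36 to -0.094 and -0.12 to 0.015. For siCont clones vs all IVF, trophectoderm, from -0.70 without female IVF embryo 4, was 0.14 with normexp, 0.011 with the floor, 0.0037 without the lowest-weighted arrays, 0.079 without female IVF embryo 2 and 0.12 without siCont clone 3. The X inactivation centre was -0.13 with no filter, and cell cycle -0.00011 with the replicate block, -0.027 without the lowest-weighted arrays or siCont clone 3 and -0.083 without female IVF embryo 4. The 2-cell list ranged from -0.17 without siCont clone 3, or the lowest-weighted arrays, to 1.04 without siCont clone 4. Without siCont clone 1, paternally expressed imprinted genes were at -0.052 (0.38 without siCont clone 3) and adhesion genes at 0.036 (-0.21 without female IVF embryo 4). Chromatin enzymes were at 0.069 without siCont clone 2 and -0.23 without siCont clone 1.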

Other observations

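The permutation tests of list medians and all tests of explanations below, except the matched-brightness test and the splits of the arrays, were chosen only after the result was seen. Against all IVF embryos, stress genes of siCont clones moved both ways. Of 17 unfolded protein and heat stress genes 9 were higher and 8 lower (median 0.15, adjusted p = 0.346), with 4 higher and 2 lower adjusted over the list alone, 0 called over all genes, and a fry test for changes in either direction at an adjusted p of 3.95e-06. Among them were the chaperones Hspa1a (2.78 ± 0.56, adjusted p = 0.0777) and Hspb1 (3.10 ± 0.77, 0.131) and the pseudokinase Trib3 (2.55 ± 0.68, 0.162). The other kept probes of Hspa1a and Trib3 were at 2.63 and 0.99. Paternally expressed imprinted genes also moved both ways (11 higher and 9 lower, median 0.16, adjusted p = 0.393, in either direction 5.58e-06, and 9.16e-05 with only the genes that had a value on every array), with Impact at 1.95 ± 0.38 (0.0692), Mest at 2.81 ± 0.72 (0.144) and Plagl1 at 2.80 ± 0.81 (0.217). Maternally expressed imprinted genes were higher for 11 of 16 (median 0.53, adjusted p = 0.168). The trophectoderm list was balanced (9 higher, 10 lower, median -0.0037, adjusted p = 0.533, turning to 0.14 with normexp and 0.12 with quantile scaling). In it, Eomes was at least 14.9-fold lower (0.0601) and Cdx2 at least 36.7-fold (0.291), above background on 1 and 3 of 4 siCont arrays, and Tfap2a at -1.68 ± 0.52 (0.219). Primitive endoderm genes were lower for 6 of 10 (median -0.76, adjusted p = 0.393), with the endocytic receptor Cubn at -2.16 ± 0.54 (0.131). The fry test in either direction also passed for the trophectoderm (0.00910), primitive endoderm (0.00193) and maternally expressed imprinted lists (0.0479, and 0.0511 with only the genes that had every value). In this comparison it passed for 15 of the 22 lists, so passing it does not single out a list.

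Other lists in siCont clones against all IVF embryos were not called in a single direction either. The fry test for changes in either direction passed for the X inactivation centre (adjusted p = 3.95e-06, and 0.0601 without Xist), interferon (0.00143), adhesion (0.0131) and cumulus genes (0.0192). The last was lost with only the genes that had a value on every array (0.521). Sperm genes were higher for 6 of 6 (median 0.81, adjusted p = 0.0749), 2-cell genes for 6 of 7 (0.65, 0.259), cumulus genes for 5 of 6 (0.27, 0.259), Sertoli genes for 11 of 15 (0.30, 0.259) and interferon response genes for 8 of 10 (1.05, 0.252). The X inactivation centre was higher for 5 of 8 (0.49, 0.303) and the cell cycle for 14 of 27 (0.11, 0.619). Escapees were lower for 4 of 4 (-0.39, 0.168), chromatin enzymes for 18 of 29 (-0.18, 0.532, although the demethylase Kdm4c was at 2.20 ± 0.54, 0.126) and adhesion genes for 12 of 21 (-0.07, 0.533). RNA interference genes had a median of -0.24, a mean of 0.04 and a test pointing down (0.393). The median per embryo differed by 2.38 for stress genes, 1.98 for maternally expressed imprinted genes and -1.29 for primitive endoderm genes (exact permutation p = 0.0286 each, the smallest they can give, adjusted p = 0.157), and in siXist clones by 1.74 for stress genes and 1.86 for maternally expressed imprinted genes at the same p. Such a median is the middle level over genes of unlike brightness, and can move without a like change of most members. The median changes of the members were smaller, at 0.15, 0.53 and -0.76 in siCont clones. In siXist clones they were -0.02 for stress and 0.33 for maternally expressed imprinted genes, and neither list was called by camera (adjusted p = 0.250 and 0.138). In the authors' table, where the median of all genes was -1.13, the medians of the lists given as higher in this paragraph, and of the stress and imprinted lists, all turned negative, between -0.989 and -0.0518. There the test passed for Sertoli (0.0384), maternally expressed imprinted (0.0329) and interferon genes (0.00782). Without siCont clone 4 the sperm (0.0312) and 2-cell (0.0302) lists passed, the first also without male IVF embryo 1 (0.0364), and without siCont clone 3 the maternally expressed imprinted list (0.0397).

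All 10 Magea and Xlr genes were lower in both clone groups than in IVF embryos, though against male IVF embryos alone the calls were lost with an estimated correlation (adjusted p = 0.0634 and 0.0650). A lower yield of genes of like brightness was argued against, since only 0.009999% of 10000 lists matched on brightness in IVF embryos, the smallest share they can give, had a median as low as -6.87 (95% of them -0.96 to 0.44). Whether the amount of Xist RNA left in the morula sets their level cannot be told apart. The upper 95% bound of siXist minus siCont clones was 2.43, below 3.63, the midpoint of the gap to IVF embryos, but siCont medians lay under the floor of -5.60 and the Xist left may suffice. The slide cannot be told apart, since 0 slides held more than 1 class.

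X-linked genes as a whole did not differ between siXist and siCont clones. The spread between embryos may hide a return to the level of male IVF embryos, since the upper 95% bound of the difference (0.574) lies above the gap of 0.198. The Xist RNA left is another candidate explanation, since its mean in siXist clones lay 6.85 in log2 above the highest male IVF embryo. Neither test excludes that Xist has little effect on these genes at this stage.

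Glycolysis genes had higher medians in both clone groups than in IVF embryos, though with an estimated correlation the call was lost in siCont clones (adjusted p = 0.0514) and, against male IVF embryos alone, in both (0.126 and 0.0650), in siXist clones also with only the genes that had every value (0.0512), and siCont medians per embryo gave an exact permutation p of 0.0571. For RNA of the Sertoli donor cell, the upper 95% bound of the Sertoli median was 1.09 at most, below the glycolysis medians of 1.30 and 1.48 (Sertoli medians 0.30 and -0.11). That bound came from resampling the genes of the list, so it leaves out the spread between embryos and cannot decide on this cause. Per embryo, the Sertoli median differed from IVF embryos by -0.10 in siCont clones (95% permutation interval -1.10 to 0.82) and -0.15 in siXist clones (-1.63 to 1.26). The glycolysis intervals, -0.03 to 2.80 and 0.69 to 2.55, overlap these. Scaling that depends on brightness was argued against, since the glycolysis median minus that of all genes was 1.03 or more under both quantile scalings. A constant per array moves all genes alike, and with that of the authors' table the siCont median against male IVF embryos was -0.29. The slide cannot be told apart (0 slides with more than 1 class), while other differences in handling between cloned and IVF embryos stay open and may contribute.

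Other splits of the same 8 arrays into 4 and 4 (35 splits) tested whether chance could give as many calls. In the comparisons with all IVF embryos these embryos were fitted as 1 class, so that real counts differ from those above. For siXist vs siCont clones chance cannot be excluded for genes (15 splits gave as many, real 2, highest other 21). For their lists and chromosomes the real count was 0, which all 35 splits reach, so nothing was tested (highest other 4 and 5). For siCont clones vs all IVF embryos only the real split gave as many gene calls (1 of 35, real 97, highest other 11). That share, 0.0286, is the smallest these splits can give and was not adjusted over the tests. It argues against chance for genes without excluding it. Chance cannot be excluded there for lists (6, real 5, highest other 7) or chromosomes (27, real 1, highest other 5). For siXist clones vs all IVF embryos only the real split gave as many gene calls (1 of 35, real 118, highest other 48), with the same limit. Chance cannot be excluded there for lists (10, real 4, highest other 6) or chromosomes (20, real 1, highest other 3).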
